A study of Pseudomonas putida with 6 samples.

How the data were processed

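The conditions of Pseudomonas putida KT2440 (urea, benzoate or cold, each in logarithmic and stationary phase) were measured as stress against control on 2-colour arrays spotted with PCR products of shotgun clones. Per the labels, RNA samples were pooled before labelling. Each condition was therefore counted as 1 sample, and its 3 or 4 hybridisations as technical repeats.

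The deposited intensity values are scanner values of the primary and secondary spot of 4543 clones in both channels, and the authors also deposited fitted intensities. Stress over control ratios are in the same deposited files, per the file headers. A separation score per clone, made by the authors, is also there and was not used. How the authors fitted the intensities is not given in the sources used here. The deposited value table of the series was matched to the signed fold of the authors' median fitted ratio, within 0.011 for 100% of the clones that have a value, and 1 cell of it is empty. It served as an alternative, on the log2 scale. Control and stress tables of an array were paired by their header numbers, which differ by 4. In every condition the channels so paired deviated together within spots (correlations from 0.31 to 0.93), and channels of different arrays did not (at most 0.048). The mean of each clone over the columns of a channel was taken off first. This lowers the values between arrays when those within spots are positive, so the low values are partly built in.

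Intensities were background-corrected with normexp (offset 50) and normalised by loess within each array, with limma 3.58.1 in R 4.3.3. Spots of a clone were averaged within an array and arrays within a condition, and ratios were expressed as stress over control. This setting, the tests, the rule for naming clones and 19 alternative settings were fixed before the data were examined. The files hold no background columns, so normexp estimated the background from the foreground values. The estimate was poor. In 22 of the 40 channel columns the fitted background SD was under 10 intensity units, and the lowest intensity of a column was 28.5% to 70.5% of its median. An offset of 50 is small on this scale. Low clones thus receive noisy, sometimes extreme ratios, whereas ratios from foreground intensities alone are drawn towards 1. Both settings had been run and their counts seen before the text was written. The foreground-only setting gave better agreement between repeats and larger counts in the model fits. It was kept as an alternative because choosing it at that point would have been a choice made on its outcome, and its counts are printed beside the main ones.

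A clone was above background when the mean of its spots exceeded the fitted background mean by 2 SD in either channel of every hybridisation. This definition was set after the files were seen. It passed 97.3% to 100% of clones per condition and so removed little. Per condition, clones were counted by size (mean log2 ratio of at least 1 in size, the same sign on every repeat, above background) with no p-value. As a technical reference, the count was repeated with the signs of 1 or more hybridisations turned, in 3 or 7 arrangements. These reference counts, and the correlations and covariances with turned signs, were added after the data were seen.

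Across conditions, limma was fitted to the 6 mean ratios, over clones above background in at least 1 condition (4543). The fits were an intercept, a mean per stress with contrasts between stresses, and phase with stress as a block, each with Benjamini-Hochberg adjustment at 0.05. With so few samples, p-values measure the spread between these conditions only. Because clones have no gene names, at most 2 higher and 2 lower clones were named per condition and per fit, those with the most extreme means among the clones that passed. Clones named otherwise were chosen after their values were seen. The 25 rows of gene lists and markers fixed beforehand could not be scored, and no list test was run, since the gene table at hand is of another strain and does not pair genes with clones.

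The scripts were tested on simulated data with 200 changed clones. The rule of size recovered 99.5% to 100% of changes of log2 1.5 and 2 among 4543 clones with 0 false calls, for independent noise. That noise was smaller than the noise between spots in the data (SD 0.34 to 0.91), and the stress channel took its floor from the control channel. These shares and false calls thus check the script and do not carry over to the data. In the fit of urea over both phases 48% of changes of log2 1 and 75% of log2 1.5 were recovered among 4543 clones, with 6 false calls each. For stationary minus logarithmic these shares were 0% and 55.5%, with 0 and 8 false calls. A change of log2 0.5 was not recovered in either. Noise in these fits was drawn independently for each clone and condition, whereas ratios in the data were related between clones. The shares and false calls of the fits thus do not carry over to the data either.

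The alternatives were foreground intensities alone, median centring, scale normalisation between hybridisations, no filter, the authors' value table, size alone, leaving out hybridisations or conditions, phase as a block, no stress block and array weights. A larger normexp offset (10000) and a stricter filter (the brighter channel at least 1.5 times the lowest value of its column) were added after seeing the data, which makes 21 settings in all.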

Results

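Pseudomonas putida is a soil bacterium that can use benzoate as a carbon source. Transcript levels of strain KT2440 were compared between stressed and control cultures for 3 stresses in 2 growth phases, which gave 6 conditions. Control cultures were kept at 26 °C in a minimal medium whose pH was 7.5 and whose sodium benzoate concentration was 15 mM. The stresses were 0.8 M urea, a denaturing solute, 45 mM sodium benzoate, and a temperature of 4 °C. Logarithmic cultures were taken at an OD600 of 0.8 and stationary cultures at an OD600 of 3.0. Each condition was measured on 2-colour arrays of 4543 shotgun clones, with 2 spots per clone and 3 or 4 repeat hybridisations, 20 in all. RNA was pooled before labelling, so a condition is 1 sample and its repeat hybridisations measure technical error only. SDs below are over these repeats. The number of arrays limits the precision. Clones carry only an identifier in the sources used here, so changes are given by clone and no gene is named.

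The first question was which clones differed between stress and control in each condition. A clone counted as different when its mean log2 ratio was at least 1 in size, with the same sign on every repeat and a signal above background in the brighter channel. This is a rule of size without a test, since no condition was replicated. The counts depended strongly on the background setting. The values given first rest on a background estimated from the spot intensities, and the foreground-only count follows each of them.

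Under urea in the logarithmic phase, 141 clones passed, 74 higher and 67 lower under stress. With foreground intensities alone 58 clones passed, 33 higher and 25 lower. Clone CC31 was lowest, with a log2 ratio of -3.36 ± 0.05 (SD, n = 3 hybridisations), which is 10.3-fold below control. GI59 was higher at 2.11 ± 0.18 (n = 3), a 4.33-fold difference. Their foreground-only ratios were smaller in size, -2.78 and 1.56. AH67 at 2.26 ± 3.58 and FU05 at -3.10 ± 3.22 (n = 3 each) also passed, but their SDs exceeded their means and their foreground-only ratios were 0.39 and -0.64. After the signs of single hybridisations were turned, at most 66 clones passed, fewer than with the signs as recorded. Without hybridisation 3 the count was 235. With a hybridisation left out, here and below, fewer signs have to agree, which makes the rule easier to pass.

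Under urea in the stationary phase, 166 clones passed, 74 higher and 92 lower. The foreground-only count was 84, with 37 higher and 47 lower. The balance turned with median centring, to 105 higher and 95 lower. GL77 was highest at 2.71 ± 0.22 (SD, n = 4), 6.52-fold above control, followed by DO75 at 2.64 ± 0.75 (n = 4). CC31 was again low at -3.10 ± 0.38 (n = 4). The foreground-only ratios of GL77, DO75 and CC31 were 2.48, 1.83 and -2.68. ED21 had the lowest mean, -4.04 ± 2.69 (n = 4), with a foreground-only ratio of -2.40. At most 106 clones passed after signs were turned.

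With 45 mM benzoate in the logarithmic phase, 91 clones passed, 59 higher and 32 lower, against 15 with foreground intensities alone, 8 higher and 7 lower. DN26 was highest at 2.26 ± 0.16 (SD, n = 3), 4.79-fold above control, and CW51 followed at 1.87 ± 0.30 (n = 3). HA62 was lower at -1.85 ± 0.20 (n = 3). With foreground intensities alone DN26, CW51 and HA62 stood at 1.55, 1.06 and -1.31. AK61 had a mean of -1.85 ± 2.82 (n = 3) and a foreground-only ratio of -0.12. Up to 623 clones passed when signs of single hybridisations were turned, far more than as recorded. Without hybridisation 1 the count was 745.

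In stationary cells with 45 mM benzoate, 43 clones passed, 16 higher and 27 lower. Foreground intensities alone gave 6, with 1 higher and 5 lower. DN26 was highest here too at 2.05 ± 0.33 (SD, n = 3), and JN33 was lowest at -2.71 ± 0.25 (n = 3), 6.55-fold below control. GX75 at 1.61 ± 1.22 and JH88 at -2.50 ± 3.40 (n = 3 each) passed with wide spreads, and their foreground-only ratios were 0.81 and -0.15. Turned signs gave up to 413 clones, and leaving out hybridisation 3 gave 510.

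At 4 °C in the logarithmic phase, 75 clones passed, 33 higher and 42 lower, and 20 with foreground intensities alone, 2 higher and 18 lower. Median centring gave 51 higher and 45 lower, and the larger normexp offset gave 38 clones, 7 of them higher. IA41 at -2.77 ± 0.16 and FY14 at -2.70 ± 0.49 (SD, n = 3 each) were the named lower clones, 6.84-fold and 6.48-fold below control. Their foreground-only ratios were smaller in size, -2.03 and -1.89. The higher clones KR64 at 2.47 ± 3.79 and AA69 at 2.39 ± 2.38 (n = 3 each) had SDs about as large as their means or larger, and foreground-only ratios of 0.17 and 0.49. Turned signs gave up to 210 clones, and leaving out hybridisation 3 gave 352.

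At 4 °C in the stationary phase, 55 clones passed, 16 higher and 39 lower, and 20 with foreground intensities alone, 3 higher and 17 lower. GN24 at -1.96 ± 0.28 and FG42 at -1.91 ± 0.33 (SD, n = 4 each) were the named lower clones, with foreground-only ratios of -1.43 and -1.47. KK20 was higher at 1.79 ± 0.99 and GL08 at 1.56 ± 1.32 (n = 4 each), with foreground-only ratios of 0.44 and 0.30. Turned signs gave up to 154 clones.

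**Figure D1:**
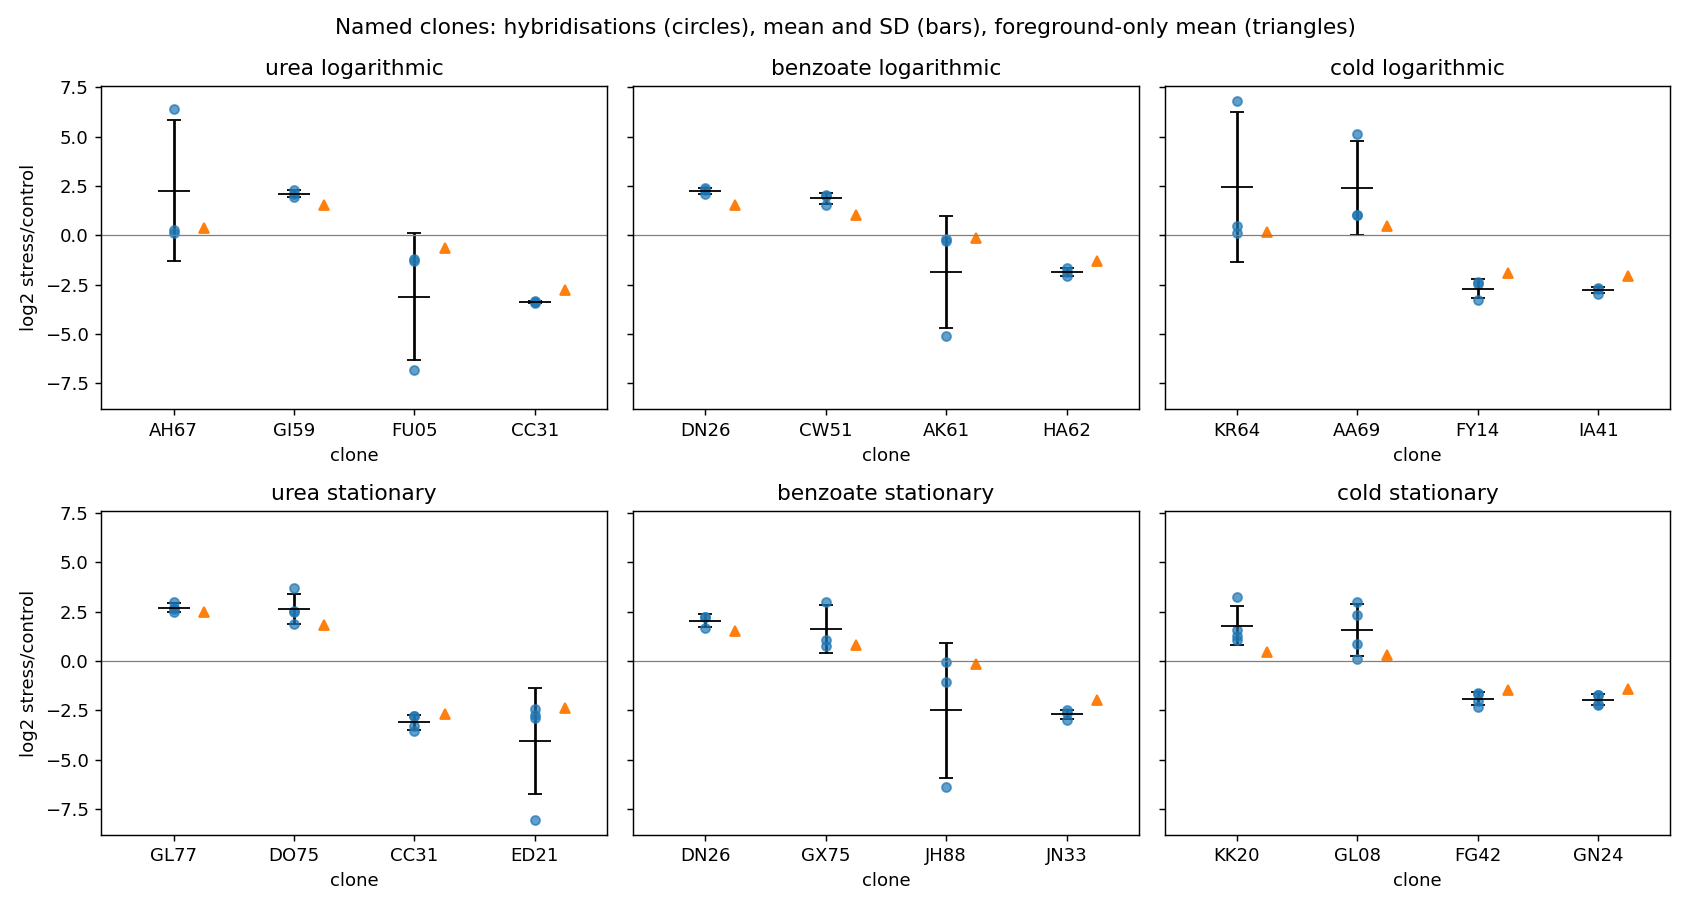
Log2 ratios of stress over control for the clones named in each condition: circles are single hybridisations, black bars the mean and SD over them, and triangles the mean from foreground intensities alone. CC31, DN26, JN33 and IA41 have tight repeats, while AH67, AK61, KR64 and JH88 rest on a single extreme hybridisation each.

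Repeat hybridisations resembled each other unevenly. Correlations across clones, which are not independent replicates, ranged from 0.05 to 0.38 under urea in the logarithmic phase and from 0.01 to 0.45 in the stationary phase. They ranged from -0.57 to 0.67 and from -0.48 to 0.75 for logarithmic and stationary benzoate, and from -0.34 to 0.21 and from -0.23 to 0.45 for logarithmic and stationary cold. With foreground intensities alone the ranges were 0.52 to 0.81 and 0.64 to 0.85 for urea, -0.06 to 0.82 and -0.06 to 0.75 for benzoate, and -0.21 to 0.37 and 0.06 to 0.59 for cold. The file headers tell the stress and control columns apart, but which dye each RNA carried on a given array is not given in the sources used here. The direction of all ratios rests on those headers, and the counts with turned signs stand beside each condition above. Over the 261 clones at least 2 times above the lowest intensity in both channels of every hybridisation, a set chosen after the data were seen, the mean covariance between repeats was positive as recorded in the benzoate and cold conditions, at 0.26 and 0.11 for logarithmic and stationary benzoate and 0.15 and 0.13 for cold.

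**Figure D2:**
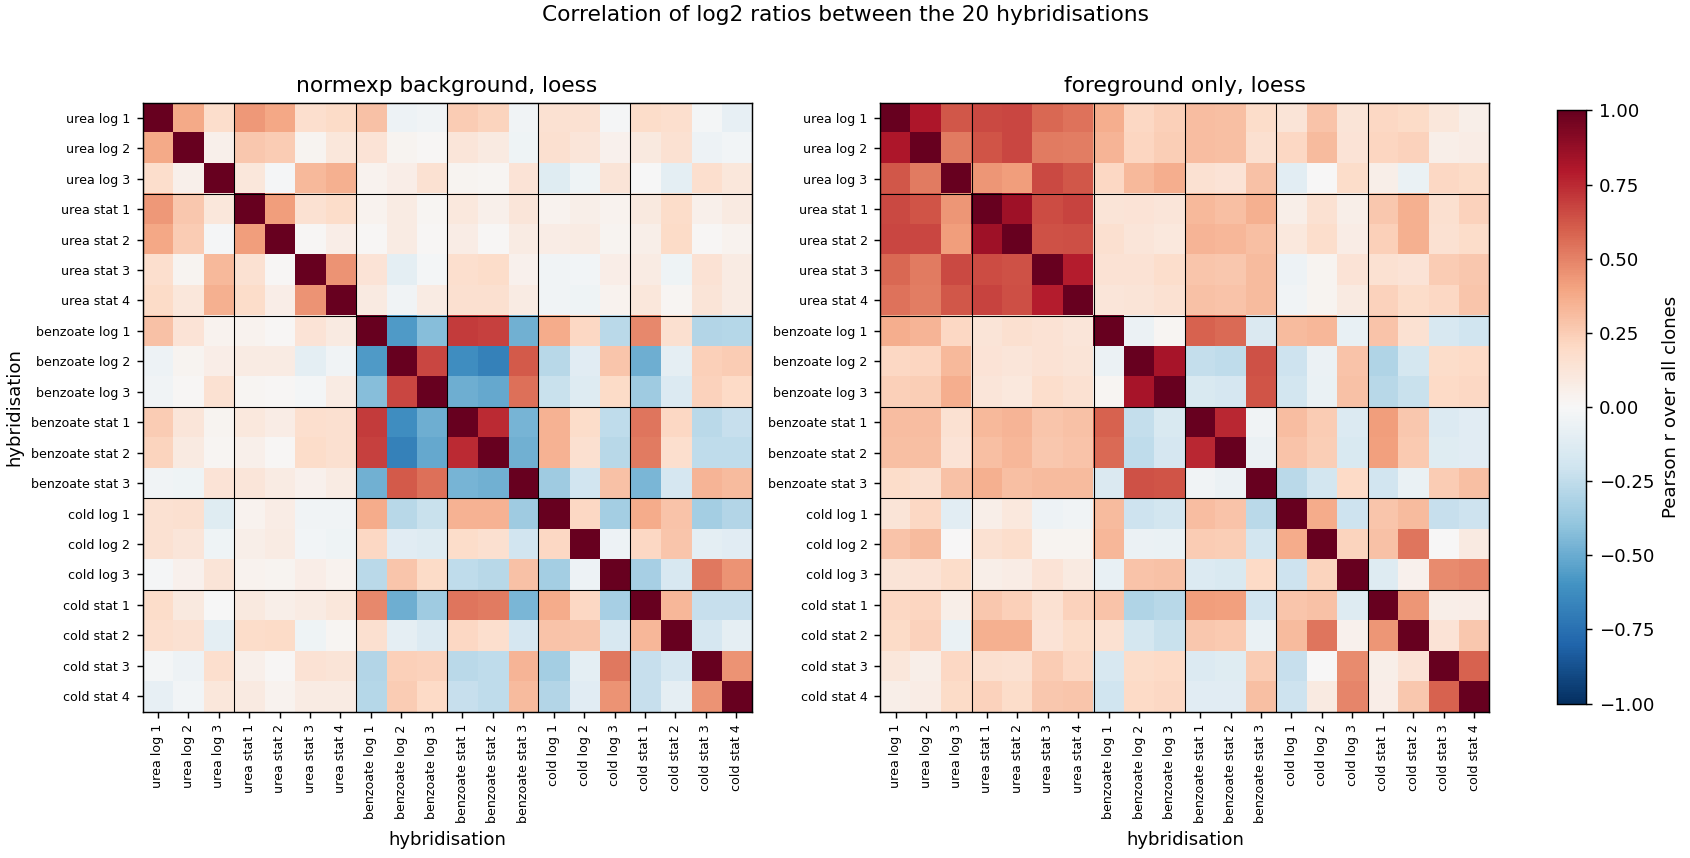
Pearson correlation of log2 ratios between the 20 hybridisations, over all clones, with background estimated by normexp (left) and with foreground intensities alone (right); black lines separate the 6 conditions. The urea repeats correlate positively throughout, and the lowest correlation among benzoate repeats is -0.57 on the left and -0.06 on the right.

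The second question was which clones moved with a stress in both growth phases. The 6 mean ratios were fitted together with limma. The 2 phases of a stress stood as its values, although they are different states and not replicates. Urea changed 65 clones at an adjusted p of 0.05, 33 higher and 32 lower, of which 31 and 27 changed at least 2-fold. CC31 fell by 3.23 on the log2 scale (SE 0.22, limma adjusted p = 0.024) and DF39 fell by 2.71 (SE 0.23, adjusted p = 0.024). GL77 rose by 2.30 (SE 0.27, adjusted p = 0.042) and GI59 by 1.85 (SE 0.18, adjusted p = 0.028). All 4 had the stated direction in both urea phases. The count was 535 with foreground intensities alone, 350 higher and 185 lower, 171 with scale normalisation between hybridisations, 117 higher and 54 lower, 5 with phase as a block and 0 with median centring, and it was 0 when any of the urea or cold conditions was left out. Under median centring the effects of the named clones were similar in size, 2.53 for GL77, 1.93 for GI59, -3.01 for CC31 and -2.49 for DF39, but none passed.

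No clone passed for benzoate or for cold over both phases in limma, with 348 and 341 clones at an unadjusted p under 0.05. Foreground intensities alone gave 34 and 56 clones. With the stationary benzoate condition left out, benzoate was represented by its logarithmic sample alone, assumed to vary like the other stresses, and 146 clones passed for that phase.

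A shift common to the 6 conditions passed for 0 clones in limma, with 566 at an unadjusted p under 0.05, and for 30 with foreground intensities alone. By sign alone, whatever the size, 398 clones moved the same way in all 6, where independent signs would give 142. The conditions may share controls, and single hybridisations of different stresses correlated at up to 0.53 (hybridisation 1 of stationary benzoate and of stationary cold). Their signs thus need not be independent. The direct comparisons of stresses gave 0 clones each in limma. The counts at an unadjusted p under 0.05 were 271 for urea minus benzoate, 298 for cold minus benzoate and 391 for cold minus urea. With foreground intensities alone 66, 18 and 169 clones passed. With the stationary benzoate condition left out, so that benzoate had 1 sample, 41 passed for urea minus benzoate and 31 for cold minus benzoate. The response in stationary minus logarithmic cells, with stress as a block, passed for 0 clones in limma, with 292 at an unadjusted p under 0.05, and for 108 with foreground intensities alone.

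The third comparison was the similarity of the profiles. The urea profiles of the growth phases had a Pearson correlation of 0.47 (Spearman 0.48) across clones, which was 0.74 with foreground intensities alone and 0.75 in the authors' value table. In both phases 71 clones passed in the same direction, 40 higher and 31 lower, where independent lists of these sizes would share 2.56. The cold profiles had a correlation of 0.21 (Spearman 0.16), which was 0.36 with foreground intensities alone and 0.33 in the authors' value table, with 16 shared clones against 0.48 by chance. The benzoate profiles had a correlation of -0.17 (Spearman -0.10), which was 0.33 with foreground intensities alone, -0.02 in the authors' value table and -0.36 with median centring, and shared 13 clones against 0.40 by chance. Pairs of single benzoate hybridisations from the different phases ranged from -0.68 to 0.70 (SD 0.63), and the correlation of the phase means from -0.52 to 0.83 over 16 arrangements of turned signs, so neither its sign nor its size is settled. With turned signs the cold value ranged from -0.39 to 0.62 and the urea value from -0.31 to 0.47, its recorded value. Different stresses in the same phase had correlations from -0.03 to 0.30 with a mean of 0.17, and across phases from -0.02 to 0.22 with a mean of 0.10. With foreground intensities alone these were 0.15 to 0.50 with a mean of 0.32, and -0.01 to 0.39 with a mean of 0.18.

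Whether conditions of a phase shared a control pool is not given in the sources used here. Simulated unchanged conditions with a shared control had a mean correlation of 0.0015 when the spread between repeats was taken off, and of 0.41 as an upper bound when it was not. The mean covariance within a phase was 0.031, against simulated values of 0.00034 and 0.081. The lower values carry little information, because the covariance left for a shared control was 0 in every same-phase pair except stationary urea with cold. These bounds enclose the value seen and do not decide whether part of the resemblance within a phase lies with the controls. The control channels themselves do not decide it either. Their differences between phases had correlations of -0.00076 for urea with benzoate, 0.11 for urea with cold and 0.032 for benzoate with cold. These channels gave 0 clones between phases (limma, 275 at an unadjusted p under 0.05). The measure may thus resolve too little for low correlations to count against a shared pool.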

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

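The larger normexp offset and the stricter filter were chosen after seeing the data. In the order urea, benzoate, cold, logarithmic before stationary, the clones passing the rule of size numbered 58, 84, 15, 6, 20 and 20 with foreground intensities alone, 58, 76, 21, 8, 24 and 20 in the authors' value table, and 217, 256, 307, 109, 143 and 85 by size alone. By size alone 262 of the 307 clones in logarithmic benzoate were higher, and 19 of the 109 in stationary benzoate. The larger offset gave 38 for logarithmic cold. Median centring, no filter, the stricter filter and otherwise the larger offset kept the main totals within 1.5 times. With median centring the balance of higher and lower clones moved, to 103 and 65 for logarithmic urea, 105 and 95 for stationary urea and 51 and 45 for logarithmic cold. Of the clones that passed, 58, 84, 15, 6, 20 and 20 also passed in the same direction with foreground intensities alone. Leaving out a hybridisation gave 145 (without hybridisation 2) to 235 (without 3), 178 (3) to 208 (1), 107 (3) to 745 (1), 41 (1) to 510 (3), 110 (2) to 352 (3) and 56 (4) to 80 (1) clones. Fewer signs then have to agree, so these counts are not at the same strictness as the main ones.

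The 65 clones of the urea fit became 535 with foreground intensities alone (62 of them shared), 0 with median centring, 171 with scale normalisation, 251 in the authors' table, 129 with the larger offset and 5 with phase as a block. The main 33 higher and 32 lower compare with 350 and 185, 117 and 54 (scale), 172 and 79 (authors' table) and 87 and 42 (larger offset). Leaving out a condition gave 0 (either urea or either cold condition) to 80 (either benzoate condition). The common shift, 0 clones, became 30 with foreground intensities alone, 1 with median centring, 29 in the authors' table, 29 with the larger offset and 11 with array weights. Leaving out a condition gave 0 to 3. For benzoate over both phases 34, 8 and 8 clones passed with foreground intensities alone, in the authors' table and with the larger offset, and 0 to 146 without a condition (146 without stationary benzoate). For cold over both phases 56 passed with foreground intensities alone and 9 in the authors' table. Urea minus benzoate gave 66 and 7 in these settings, cold minus benzoate 18 and 6, cold minus urea 169 and 65, and stationary minus logarithmic 108 and 5. With the larger offset 4 passed for cold minus urea. Without stationary benzoate, urea minus benzoate gave 41 and cold minus benzoate 31, and 0 without any other condition. For cold over both phases, cold minus urea and stationary minus logarithmic 0 clones passed whichever condition was left out. Where a condition was left out, its stress had 1 sample, assumed to vary like the others.

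The correlation of the urea phases was 0.74 with foreground intensities alone, 0.75 in the authors' table and 0.66 with the larger offset. That of the benzoate phases turned from -0.17 to 0.33 with foreground intensities alone. Of 96 alternative values of the clones named per condition, 63 lay within 1 SD of the main value, 33 moved further and 0 changed sign. This SD was above 1 for 9 of the 24 values, so being within it says little there, and 15 of the 24 were at least 1 in size with foreground intensities alone. The causes of these shifts were not tested. Signal over background may limit the ratios of dim clones in any setting, but brighter and dimmer clones were compared under the main setting only. Alternatives for gene lists were not run, since clones have no gene names, nor was a slide or scan date block, as the files give neither. No paired analysis was possible because, for pairing by replicate number, each condition holds 1 sample. Pairing of phases within a stress and of stresses within a phase is the stress or phase block given above.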

Other observations

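All tests in this part were chosen after the results were seen.

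Across the 6 conditions 369 clones passed the rule of size at least once, with the directions of the hybridisations as recorded. CC31, also named for urea, was the 1 clone that passed in 6 conditions, lower in each, with log2 ratios from -3.36 to -1.04. In stationary benzoate its ratio was -0.83 with foreground intensities alone and -0.73 in the authors' value table, and in stationary cold -0.91 in that table, so it falls short of the size rule there. DF39 was lower under urea (-2.46 and -2.95) and cold (-1.68 and -1.85) in logarithmic and stationary cells, and stood at 0.50 and -0.25 under benzoate. JP83 passed as higher in both urea phases (1.04 in logarithmic cells) and in stationary benzoate (1.17), and as lower under cold (-1.08 and -1.01). These clones were singled out after their values were seen.

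Repeat hybridisations of 1 condition disagreed with each other. The lowest correlation was -0.57 in logarithmic benzoate, and with foreground intensities alone -0.21 in logarithmic cold. Channels exchanged in dye between repeats are a candidate explanation. Over the 24 pairs of repeats, a larger gap in the control-over-stress ratio of the lowest intensities went with a lower correlation of the pair (rank correlation -0.20, one-sided permutation p = 0.018 with hybridisations shuffled within conditions; -0.047 and p = 0.010 with foreground intensities alone). The test does not decide, because the trend does not single out the pairs that disagreed. The pairs furthest apart in this ratio were urea repeats, which correlated positively. Hybridisations 1 and 3 in logarithmic urea stood at log2 1.21 and -1.64, with a correlation of 0.17. Within urea the trend did hold, since hybridisations 1 and 2 there (1.21 and 1.49) correlated at 0.38. In stationary urea, hybridisations 1 and 2 (1.57 and 1.61) correlated at 0.42, and 3 and 4 (-1.61 and -1.15) at 0.45. Stationary urea pairs on opposite sides stood at 0.01 to 0.18. In logarithmic cold, hybridisations 1 and 2 were furthest apart (log2 -0.97 and 0.45) and had that condition's highest correlation, 0.21. The foreground-only rank correlation was also slight. Noise of clones near the intensity floor may lower these correlations, since repeats correlated better over the brighter clones than over the dimmer ones in 6 of 6 conditions. For logarithmic benzoate the means were 0.36 and -0.21. Independent noise alone would not make a correlation negative. Over the dimmer clones the means were -0.21 and -0.17 for benzoate and -0.15 and -0.11 for cold, logarithmic before stationary. This argues against noise as the whole explanation in benzoate and cold. Some hybridisations resembled those of another condition more than their own repeats. Hybridisation 1 of logarithmic benzoate correlated at -0.57 and -0.43 with its repeats. With hybridisation 1 of stationary benzoate it stood at 0.70, and with that of stationary cold at 0.48. With foreground intensities alone these were -0.06, 0.02, 0.59 and 0.28. What such hybridisations share was not tested. Exchanged dyes and a share of noise stay open, and neither excludes the other. No biological explanation was tested, because the repeats come from the same RNA pools.

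With directions as recorded and the same sign required on every repeat, more clones passed under urea (141 and 166) than under benzoate (91 and 43) or cold (75 and 55). Urea was also highest with foreground intensities alone and in the authors' value table. The order does not hold in general, since by size alone logarithmic benzoate was highest with 307. Turned signs gave up to 623 and 413 clones for benzoate and 210 and 154 for cold. Those counts bear on the order only if the recorded directions of the turned hybridisations are wrong. Noise of the urea hybridisations is argued against by the covariance between urea repeats, at least 0.088 (95% bootstrap interval over clones 0.073 to 0.10), which exceeded the highest recorded value of the other 4 conditions by 0.083. Bootstrap intervals here treat clones as independent, although clones that share a prefix had related ratios, so they may be too narrow. They hold no spread between samples. With turned signs the others reached 0.59, so over all clones the excess of urea rests on the recorded directions. Distortion of the other conditions by the intensity floor is argued against as the whole cause by the 261 clones at least 2 times above the lowest intensity in both channels, over which the difference was 0.11 (0.038 to 0.21), with recorded and with turned signs. That minimum was lowered from 5 times, at which 13 clones were left. An unrecorded dye arrangement in the benzoate and cold arrays stays open, as does a wider response to urea, which may be read as a hypothesis only.

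Clones that share the first letters of their identifier had related ratios. The 267 prefixes accounted for 29.1% and 26.4% of the variance (adjusted) in logarithmic and stationary benzoate and 15.5% and 6.25% in cold, against 3.42% and 1.31% in urea. With foreground intensities alone these were 11.6% and 9.33%, 14.5% and 4.96%, and 0.77% and 0.73%, so logarithmic cold was then highest. Among 100 shuffles of the identifiers the highest value of any condition was 1.71%, in logarithmic urea. What the prefixes stand for is not given in the sources used here.

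For growth phase, the 3 against 3 conditions allow 10 splits, too few for a share under 0.05. The real split gave 0 clones (limma, 292 at an unadjusted p under 0.05), and the highest other split gave 115. With a real count of 0, the 10 splits reach it by construction and say nothing of chance. With stress as a block, the split with 115 clones compares the benzoate phases alone. For the shift common to the 6 conditions, the real count was 0 (limma, 566 at an unadjusted p under 0.05), so that the 32 arrangements of signs decide nothing either. The highest other gave 1. The control channels alone, compared between stationary and logarithmic cells after quantile normalisation, gave 0 clones (limma, 275 at an unadjusted p under 0.05), with 2 in the highest other of the 10 splits. Phase differences of the control channels hardly correlated between the stress series (-0.00076, 0.11 and 0.032).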
